A study of Homo sapiens with 6 samples.

How the data were processed

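One table per library was used, for 3 shControl and 3 shGPER libraries of SNU668 cells, grouped by the titles in the labels. Libraries were made from total RNA with a stranded mRNA kit with ligation, per the labels' protocols. The values deposited by the authors are TPM per gene, with gene descriptions, biotypes and annotation terms in the same table. The submitters' processing notes name fastp, HISAT2, RSEM and the build hg38, with no version, order or settings, and whether strand was used in counting is not given in the sources used here. All 6 tables list the same 2128 genes. Because these genes sum to 4.66 to 6.42% of the total to which TPM are scaled, most of each library's expression was not analysed here. TPM divide by the total of the library and by transcript length, so a change in a few abundant transcripts shifts all others, and read depth cannot be recovered; no counting error or detection limit is given for this reason, and no count model was used.

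Log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (shGPER minus shControl, intensity trend in the variance prior, no robust option, no covariate), on 1651 genes with a TPM of at least 1 in at least 3 of the 6 libraries; 477 genes were left out. P-values were two-sided and adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05, and a 2-fold change is a log2 change of 1. A fold change on this scale understates the change of genes of low TPM. A gene under 1 TPM in all libraries of a group passed the filter only through the other group, so its direction was fixed by the filter. On simulated data with the real means and spreads of the 1651 genes, the fit recovered 80.6%, 95.5% and 98.5% of genes changed by a log2 fold of 0.5, 1 and 2, and called 15 of 1451 unchanged genes. Most simulated genes were unchanged, whereas nearly all tested genes of the real data were called. These rates check the fit and do not describe the calls below. Gene lists, 39 in all, were written before the data were examined. Those with at least 5 tested members (7 lists) were tested with camera (preset inter-gene correlation 0.01), with an estimated correlation and with fry. Camera compares a list with the other genes of the table alone, and since that table was already selected, its p-values describe the position of a list among selected genes. A further 25 lists had 1 to 4 tested members and are described by counts.

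Genes are named by a rule fixed before the data were examined. It takes GPER1, the 12 genes with the largest rise and the 12 with the largest fall among called protein-coding genes with a symbol, a mean of at least 5 TPM in a group and no overlap between the groups, and 12 genes of the Hippo pathway and related biology whatever their result. From each list described it takes up to 4 tested members with the smallest p; a symbol with several entries is represented by the one with the highest mean TPM. CDX2, KLF2, WWC1 and the genes outside this rule in the closing part were named after their values were seen.

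Positions, transcript lengths and GC content come from GENCODE release 29 (GRCh38, the assembly also called hg38); 2078 of the 2128 gene identifiers matched, and 98.5% of the called genes had a GC value. A gene's GC content is the median over its annotated transcripts. To ask whether a group of genes rose more often than its GC content would give, called genes were split into 10 strata of GC content, and an exact test on the number that rose per stratum was used. With the direction of each gene drawn separately from GC content alone, 2.67% of 300 simulated sets of 15 low-GC genes gave p under 0.05. This does not cover genes that move together. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

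The alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median centring, quantile normalization, no intensity trend, a robust prior, a replicate block and leaving out each library in turn. The removal of a trend with GC content was added after the data were examined. It used a natural spline with 3 degrees of freedom fitted to each library's deviations from the gene means. The spline was fitted to the tested genes of this selected table, nearly all of which were called. Its removal can therefore also take out a difference between the groups that is not a bias.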

Results

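RNA-seq was performed on SNU668, an established cell line of gastric signet-ring cell carcinoma. In all, 3 libraries are titled as short hairpin RNA controls (shControl) and 3 as hairpin knockdown (shGPER) of GPER1, the gene of the G protein-coupled estrogen receptor. Expression was given as TPM, the share of each gene among all transcripts of a library scaled to a fixed total, for a partial set of genes, of which 1841 were protein-coding and 203 were long non-coding RNAs. These genes summed to 61181 to 64236 TPM in the shControl libraries and to 46584 to 49148 TPM in the shGPER libraries, 4.66 to 6.42% of the total to which TPM are scaled. TPM keep no count of reads, so the depth of each library is unknown. The 3 shGPER values lay wholly above or wholly below the 3 shControl values for 95.3% of the genes, against 10% by chance. The table therefore held mostly genes that separated the groups, by a rule not given in the sources used here. The tests below are not independent evidence that these genes differed. Small changes were nearly absent as well. Of 1164 genes with a mean of at least 5 TPM in a group, 5 had a log2 ratio of mean TPM within 0.5 of 0. The labels also call the control cells wild type, so that it is uncertain whether these carried a control hairpin. The labels do not say whether 1 or several hairpins were used, so effects of GPER1 loss and off-target effects of a hairpin cannot be separated. They do not say either whether libraries of a group came from separate cultures, and the p-values measure only the spread between these libraries.

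The first question was whether the targeted gene was lower in the cells with its hairpin. GPER1 (ENSG00000164850; chromosome 7, 1082208 to 1093815, plus strand, GRCh38) was present at 10.41 to 11.04 TPM in the shControl libraries and at 1.83, 2.41 and 2.47 TPM in the shGPER libraries. The means were 10.8 ± 0.353 and 2.24 ± 0.354 TPM (SD, n = 3 each), so that 20.7% of the control level was left. GPER1 fell by 1.87 on the log2(TPM + 1) scale (SE 0.11; limma, adjusted p = 1.14e-06). The two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow.

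The title of the study names the Hippo/YAP axis, and the genes of that pathway came next. YAP1 and WWTR1, which encodes TAZ, are the transcriptional coactivators that the Hippo kinases hold in check, and both fell in shGPER cells. YAP1 (ENSG00000137693; chromosome 11, 102110461 to 102233423) went from 11.9 ± 0.783 to 6.38 ± 0.796 TPM (SD, n = 3 each), a log2 fold change of -0.81 (SE 0.10; limma, adjusted p = 8.64e-05). WWTR1 (ENSG00000018408; chromosome 3, 149517235 to 149736714) went from 10.2 ± 0.836 to 5.70 ± 1.06 TPM, a log2 fold change of -0.75 (SE 0.13; limma, adjusted p = 0.000627). All 3 tested members of the list of 22 YAP/TAZ target genes fell as well. They were AMOTL2, an angiomotin-family scaffold, with a log2 fold change of -0.99, NT5E, the ecto-5'-nucleotidase CD73, with -0.96, and ASAP1, an ARF GTPase-activating protein, with -0.82. From their GC content 1.78 of the 3 would fall (exact stratified p = 0.0589, adjusted over 32 lists 0.433).

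**Figure D1:**
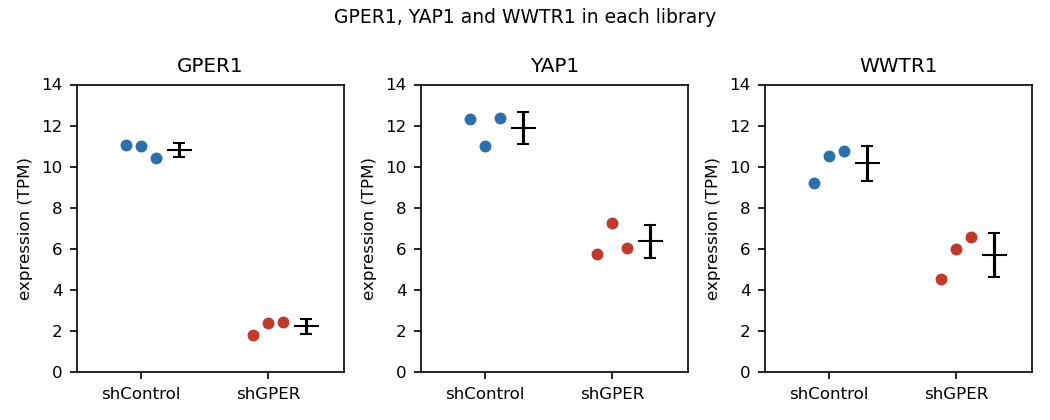
Expression in TPM of GPER1, YAP1 and WWTR1 in each of the 3 shControl (blue) and 3 shGPER (red) libraries, with the mean and SD of each group beside the points. The shGPER values lie below all shControl values for each gene, with group means of 10.8 and 2.24 TPM for GPER1, 11.9 and 6.38 TPM for YAP1, and 10.2 and 5.70 TPM for WWTR1.

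Of 7 tested Hippo pathway components, 5 fell and 2 rose. FRMD6, an upstream regulator of the pathway, fell from 32.9 to 14.5 TPM, the kinase gene STK3, which encodes MST2, from 8.74 to 4.90 TPM, and the kinase gene TAOK3 from 12.7 to 6.27 TPM. TEAD2, a DNA-binding partner of YAP and TAZ, rose from 5.09 to 14.6 TPM, and WWC1, the scaffold KIBRA, from 2.12 to 4.27 TPM. As a list, the components did not differ from the other genes of the table (camera, adjusted p = 0.415). Of the 12 genes named in advance whatever their result, YAP1, WWTR1 and CDH1 were listed; CDH1, which encodes E-cadherin, was at 0.533 ± 0.153 and 0.233 ± 0.164 TPM (SD, n = 3 each), below the level for testing. TEAD1, TEAD4, LATS1, LATS2, CCN1, CCN2, ANKRD1, AXL and ESR1 were not analysed here. When the trend of each library with transcript GC content was removed, YAP1 and TAOK3 lost their call (adjusted p = 0.895 and 0.682; YAP1 log2 fold change 0.02), STK3 was called higher (0.20, adjusted p = 0.0332) and WWTR1 stayed lower (-0.84). Of the YAP/TAZ targets AMOTL2 alone stayed called (-2.08). The trend was estimated from these selected genes, so its removal compares a gene with other changed genes of like GC content. Here and below, a call lost or turned by it does not show that a gene was unchanged.

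Across the table, 1651 genes reached 1 TPM in at least 3 libraries and were tested. In shGPER cells 789 genes rose and 836 fell (limma, adjusted p under 0.05), and 26 passed in neither direction. On the log2(TPM + 1) scale, 528 of these rose and 399 fell by at least 2-fold. This balance depends on the scaling, with 725 and 216 after median centring, and the counts depend on the pseudocount, with 741 and 552 at 0.1. Since small changes were nearly absent from the table, the 2-fold counts may largely restate its selection. Without the GC trend 512 rose and 506 fell, and 964 of the 1600 called genes with a GC value kept their call and direction.

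The genes that rose most included several of the regulated secretory pathway of neuronal and endocrine cells. VGF, a neuropeptide precursor, rose from 2.89 ± 0.20 to 40.7 ± 5.62 TPM (SD, n = 3 each), SYP, the vesicle protein synaptophysin, from 2.97 to 30.9 TPM, SCG2, the granule protein secretogranin II, from 3.74 to 26.5 TPM, and CPLX1, a complexin that acts in vesicle fusion, from 4.14 to 27.8 TPM. HMOX1, the heme-degrading enzyme heme oxygenase 1, was the most abundant of the 12 genes with the largest rise and went from 37.9 ± 1.65 to 341 ± 31.4 TPM (log2 fold change 3.13, SE 0.07; limma, adjusted p = 5.53e-08). COL1A1, a chain of type I collagen, rose from 2.83 to 29.4 TPM, MKNK2, a kinase of the translation factor eIF4E, from 42.4 to 271 TPM, and RGS19, a regulator of G protein signaling, from 2.74 to 22.1 TPM. RTN2, a reticulon, and LMTK3, a lemur tail kinase, reached 27.8 and 16.4 TPM, with log2 fold changes of 3.05 and 2.39. ZNF468, a zinc finger gene, rose from 3.60 to 28.8 TPM, and the endonuclease gene SLX1B from 3.90 ± 3.39 TPM with a log2 fold change of 2.84 (SE 0.71). Both are uncertain, since ZNF468 shares 54.1% of its 31-nt words with ZNF320 and SLX1B has a near-identical copy, SLX1A; SLX1B also varied between libraries, with a log2 fold change of 1.75 (SE 0.75) without the GC trend that was not called (adjusted p = 0.0786).

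The 12 genes that fell most had varied functions. RAD23B, which carries ubiquitinated proteins to the proteasome and acts in DNA repair, fell from 78.7 ± 1.75 to 8.79 ± 0.225 TPM (SD, n = 3 each; log2 fold change -3.02, SE 0.06; limma, adjusted p = 4.25e-08). EIF1AX, a translation initiation factor, fell from 92.6 to 13.8 TPM, MRPL9, a mitochondrial ribosomal protein, from 61.6 to 9.34 TPM, and IARS2, the mitochondrial isoleucyl-tRNA synthetase, from 86.4 to 13.2 TPM. DPY30, a subunit of histone H3 lysine methyltransferases, fell from 99.2 to 16.4 TPM, NDFIP1, an adaptor of NEDD4-family ubiquitin ligases, from 36.9 to 6.05 TPM, and KIF5B, a kinesin heavy chain, from 58.0 to 10.3 TPM. The remaining genes of this set, CCDC34, YIPF1, TMEM35B, SLC30A9 and ERGIC2, had log2 fold changes of -2.59, -2.51, -2.51, -2.40 and -2.39.

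**Figure D2:**
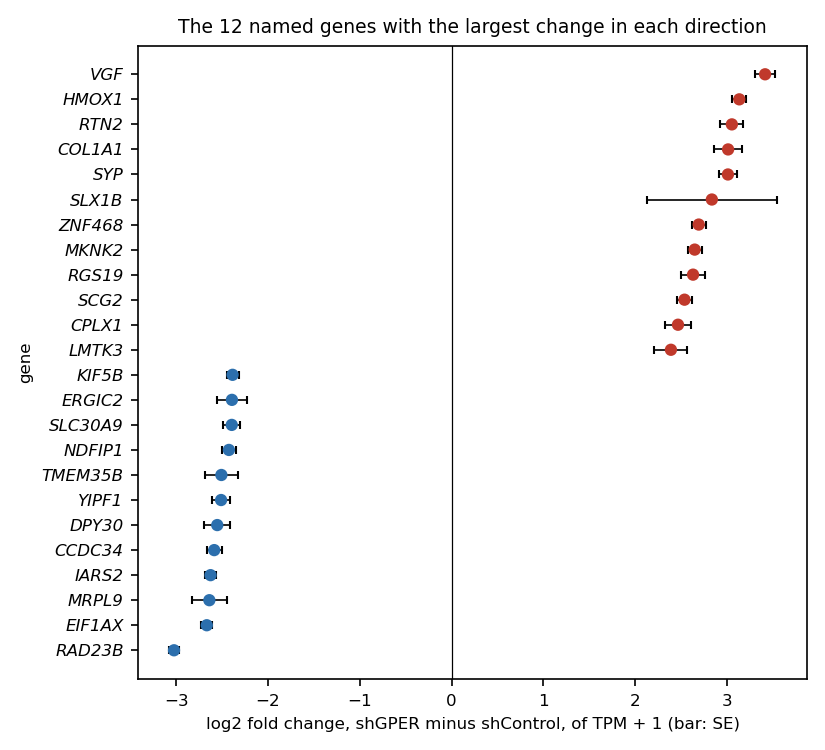
Log2 fold change of TPM + 1 (shGPER minus shControl, 3 libraries each; bars are the SE) for the 12 named genes with the largest rise (red) and the 12 with the largest fall (blue). Values run from 3.42 for VGF to -3.02 for RAD23B, and SLX1B has the widest error bar.

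The tested genes of the G2/M and G1/S phase lists were lower in shGPER cells. All 15 tested G2/M phase genes fell, with a median log2 fold change of -0.98. MKI67, the proliferation marker Ki-67, fell from 102 ± 0.538 to 26.3 ± 2.99 TPM (SD, n = 3 each), CENPF, a kinetochore protein, from 49.5 to 15.7 TPM, ANLN, an actin-binding protein of cytokinesis, from 95.7 to 30.4 TPM, and UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, from 305 to 156 TPM. All 4 tested G1/S phase genes fell, among them UNG, a uracil-DNA glycosylase, at a log2 fold change of -1.33 from 39.4 TPM, and CCNE2, cyclin E2, from 6.48 to 2.65 TPM. CCND1, cyclin D1, the sole tested member of the ERK output list and a member of the Wnt and Notch lists, fell from 95.5 to 44.2 TPM. The G2/M list was lower than the other genes of the table (camera, adjusted p = 0.000377), with an adjusted p = 0.0871 with an estimated correlation. From their GC content 12.5 of the 15 G2/M genes would fall (exact stratified p = 0.0675, adjusted over 32 lists 0.433). Without the GC trend the G2/M list had an adjusted p of 0.0585 (camera) and a median log2 fold change of -0.24. Of its 15 genes 7 stayed lower and none was higher, and 1 of the 4 G1/S genes stayed lower.

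Next came the immediate early, CREB and PI3K and FOXO lists. Of 6 immediate early genes 5 rose, among them the nuclear receptor genes NR4A2, from 3.82 to 18.9 TPM, and NR4A1, from 3.90 to 14.4 TPM, and FOSB, an AP-1 subunit, from 0.50 to 2.77 TPM; KLF2, at 0.777 and 1.19 TPM, was not called. All 5 tested genes of the cyclic AMP and CREB list rose, and 3 of these (NR4A2, NR4A1 and FOS) are also immediate early genes. CGA rose from 0.297 to 1.69 TPM. FOSB and CGA were under 1 TPM in all shControl libraries, so the filter fixed their direction. All 5 tested genes of the PI3K and FOXO list rose, including FBXO32, the ubiquitin ligase atrogin-1, from 4.81 to 15.3 TPM, ERBB3, a receptor of the EGF receptor family, from 5.52 to 11.5 TPM, KLF9 from 1.16 to 2.86 TPM and PDK4, a kinase that inhibits pyruvate dehydrogenase, from 1.26 to 3.38 TPM. None of the 3 lists passed as a list (camera, adjusted p = 0.0506, 0.0506 and 0.0575), and with an estimated correlation the adjusted p were 0.323, 0.249 and 0.249. Without the GC trend 4 immediate early genes, 3 CREB genes and all 5 PI3K and FOXO genes stayed higher, and KLF2 was called lower.

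Inflammatory and cytoskeletal genes went both ways. Of 6 tested NF-kB and cytokine genes 3 fell, the chemokine CCL2 from 81.6 ± 4.16 to 20.8 ± 2.65 TPM (SD, n = 3 each), the cytokine IL6 from 156 to 75.8 TPM and the chemokine CXCL8 from 99.3 to 53.6 TPM, while 3 rose, including the NF-kB subunit RELB from 10.3 to 22.6 TPM. Of 6 actin cytoskeleton and focal adhesion genes 4 rose, among them the tropomyosin TPM4, from 37.0 to 176 TPM, the GTPase RHOB, from 10.7 to 30.7 TPM, and the calponin CNN2, from 23.2 to 58.6 TPM; 2 fell, including the caldesmon gene CALD1, from 40.0 to 11.2 TPM. Neither list differed from the other genes of the table (camera, adjusted p = 0.810 and 0.411). CXCL8 and RELB lost their call without the GC trend, at log2 fold changes of 0.04 and -0.01.

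**Figure D3:**
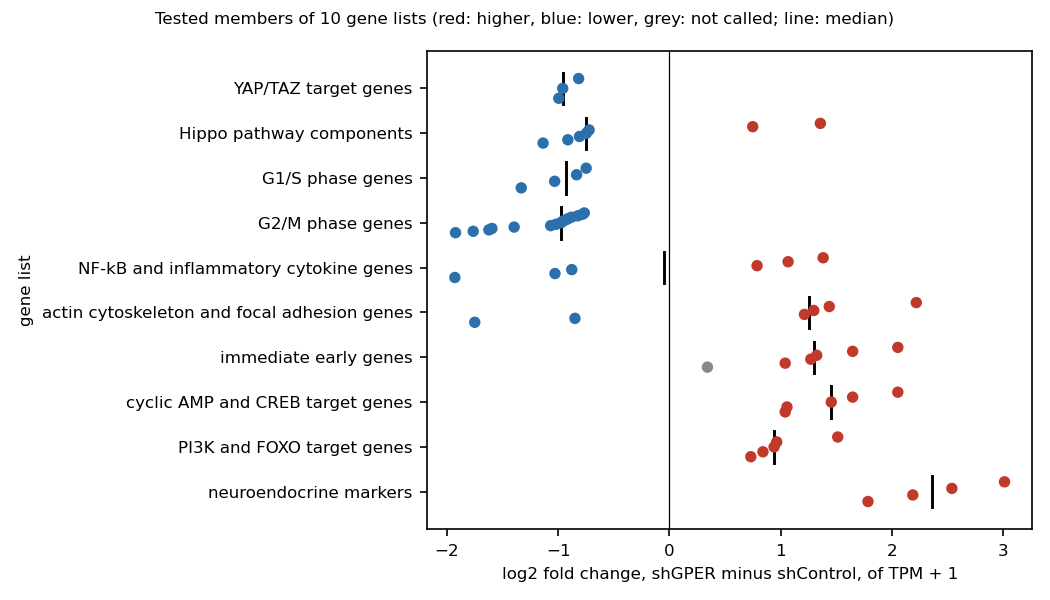
Log2 fold change of TPM + 1 (shGPER minus shControl) of each tested member of 10 gene lists; points are genes, colored by call, and the black line is the list's median. All 15 G2/M phase genes lie below 0 and all 4 neuroendocrine markers above 0, while the 7 Hippo components split into 5 lower and 2 higher.

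Adhesion and surface genes had fewer members in the table. The 3 tested epithelial junction genes rose, the plakoglobin gene JUP from 78.5 to 196 TPM, the plakophilin gene PKP3 from 36.7 to 78.0 TPM and TJP3 from 3.03 to 9.78 TPM, and without the GC trend 1 of the 3 stayed higher. Of 4 extracellular matrix genes 3 fell, including the laminin genes LAMC1, from 119 to 45.6 TPM, and LAMB1, from 12.7 to 6.79 TPM; COL7A1 rose from 1.15 to 1.84 TPM but was lower without the GC trend (log2 fold change -0.59). Its call was also lost with a pseudocount of 0.1, with quantile normalization (-0.0429) and without any 1 of 4 libraries (shControl 2 or 3, shGPER 1 or 3). The hyaluronan receptor CD44 fell from 673 to 265 ± 18.4 TPM (SD, n = 3). It was 1 of 3 stemness genes that fell, with CD24, from 143 to 72.8 TPM, and ALDH1A3, from 9.76 to 5.59 TPM, while EPHB2 rose from 2.27 to 4.22 TPM. Both tested mesenchymal genes, COL1A1 and TAGLN, rose. TAGLN was under 1 TPM in all shControl libraries, so the filter fixed its direction. TAGLN and EPHB2 lost their call without the GC trend. Of 4 estrogen receptor and target genes, IGFBP4 rose from 166 to 453 TPM and RARA from 5.97 to 17.2 TPM, whereas TFF1, a gastric trefoil peptide, fell from 5.10 to 1.80 TPM, as did GPER1 itself. Without the GC trend the log2 fold change of IGFBP4 shrank from 1.446 to 0.45 and that of RARA from 1.375 to 0.38, both still called. Those of TFF1 and GPER1 were then -1.77 and -2.81.

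Among lists of stress and cell death, the 3 tested p53 target genes rose, namely BTG2, from 42.7 to 104 TPM, GDF15, from 25.8 to 59.7 TPM, and BBC3, which encodes the BH3-only protein PUMA, from 16.2 to 39.9 TPM. From their GC content 2.38 of the 3 would rise (exact stratified p = 0.541), and without the GC trend BTG2 stayed at a log2 fold change of 1.33 while GDF15 and BBC3 fell back to 0.23 and 0.19, still called. Among apoptosis regulators BCL2A1 rose from 0.233 to 1.15 TPM and BCL2L2 fell from 16.7 to 9.27 TPM. Of 3 integrated stress response genes TRIB3 and CEBPB rose, the latter from 56.8 to 203 TPM, and CEBPG fell from 26.9 to 12.5 TPM. The log2 fold changes of TRIB3, CEBPB and CEBPG were 1.27, 1.81 and -1.045. Without the GC trend they shrank to 0.29, 0.72 and -0.16, still called. Of 4 interferon response genes BST2 and IRF7 rose and IFIT1 and IFIT3 fell, and of 4 Wnt target genes FZD7 and NKD2 rose and CCND1 and DKK1 fell. Smaller lists had 1 or 2 tested members. HMOX1 of the NRF2 list, NOTCH3 of the Notch list and GALNT6 of the mucin list rose. NOTCH3, like BCL2A1 above, was under 1 TPM in all shControl libraries, so the filter fixed its direction. TFF1, the other tested member of the mucin list, fell as given above. ID1 of the TGF-beta list, KDM3A of the hypoxia list, FADS1 of the fatty acid list, MSMO1 and STARD4 of the cholesterol list and the histone gene H2BC12 fell. Without the GC trend IFIT1, IFIT3, NKD2, DKK1, NOTCH3, GALNT6, KDM3A, MSMO1 and STARD4 lost their call. The histone gene H3C10 was not called at 2.35 ± 0.609 and 2.30 ± 0.991 TPM (SD, n = 3 each).

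Marker lists of other cell types had too few tested members for camera and are given by gene. All 4 tested neuroendocrine markers rose, SYP and SCG2 as above, SCG3 from 0.14 ± 0.0624 to 4.19 ± 0.204 TPM and CHGB from 0.233 ± 0.139 to 3.23 ± 0.0721 TPM (SD, n = 3 each). Of 3 fibroblast markers COL1A1 rose and LUM and DCN, at 2.52 and 2.73 TPM in shControl, fell to 1.20 and 1.36 TPM; LUM and DCN lost their call without the GC trend. Of 2 endothelial markers CDH5 rose from 1.63 to 7.29 TPM, and ERG, at 0.737 and 1.01 TPM, was not called, though it was called higher after median centring (log2 fold change 0.48) and without the GC trend (0.86). The table held no member of 6 lists, those of leukocyte markers, antigen presentation, the unfolded protein response, heat shock, mitochondrially encoded mRNAs and cytosolic ribosomal proteins, and its intestinal gene CDX2 was below the level for testing. In the 32 lists with a tested member, the counts adjusted over the list alone were the same as those over all tested genes.

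Direction followed the base composition of the transcripts. The median GC content was 59.6% for genes that rose and 44.3% for genes that fell. In the tenth of called genes with the lowest GC content (33.7 to 39.8%) 4.38% rose, and in the tenth with the highest (64.0 to 73.8%) 94.4% rose. The log2 ratio between the groups rose by 0.84 for each 10 percentage points of GC content, with a rank correlation across genes of 0.59; genes are not independent replicates. Between 2 libraries of the same group the steepest such slope was 0.12, between shGPER libraries 1 and 3. The rank correlation for that pair was 0.49, near that between the groups, so the shGPER libraries also differed from each other by GC content. Among shControl libraries the largest in size was -0.12, between libraries 2 and 3. The G2/M genes, with a median GC content of 42.3%, moved with this relation, whereas GPER1, at 61.2%, and the neuroendocrine markers SCG2 and SCG3, at 43.3 and 41.9%, went against it.

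**Figure D4:**
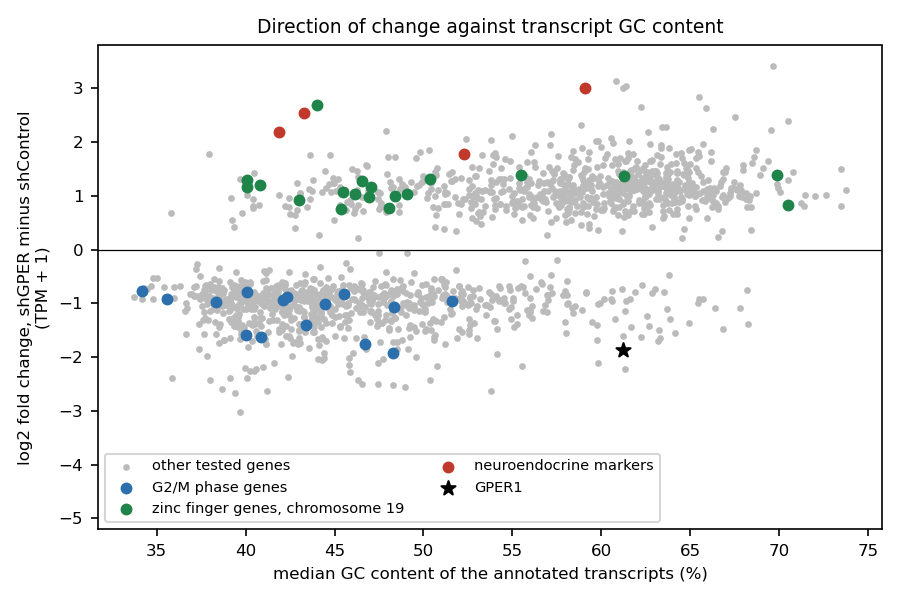
Log2 fold change of TPM + 1 (shGPER minus shControl) of the tested genes against the median GC content of their annotated transcripts in percent; each point is a gene, and the colored points mark the G2/M genes, the zinc finger genes of chromosome 19, the neuroendocrine markers and GPER1. Genes of low GC content lie mostly below 0 and genes of high GC content mostly above 0, with medians of 44.3% for those that fell and 59.6% for those that rose.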

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

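The removal of the GC trend was chosen after the data were examined; the other settings were fixed before. GPER1 fell under all 16 alternatives, with log2 fold changes between -2.81 (GC trend removed) and -1.61 (median centring). Of 105 named genes, 101 kept their direction and their side of the threshold under each setting other than GC removal in which they were tested. The filter of 5 TPM left 438 genes that rose, since fewer genes were tested. Median centring shifted the median log2 fold change by 0.27 and left 725 genes that rose and 216 that fell by at least 2-fold, against 741 and 552 with a pseudocount of 0.1; the histone gene H3C10 turned to 0.21 and ERG was called higher (0.48), as with the GC trend removed (0.86). Quantile normalization turned COL7A1 to -0.0429 and ERG to -0.23, ended the call of GALNT6 (0.26), and gave an adjusted p of 0.0442 for the immediate early and the CREB lists; without the intensity trend these and the PI3K and FOXO list had 0.0465. Fry asks whether a list's genes move one way and compares them with no other gene. Its adjusted p were 0.000797 for the Hippo components, 0.000119 for the immediate early genes and 1.45e-05 for PI3K and FOXO. For CREB, actin and NF-kB they were 0.000108, 0.000693 and 0.000762. Because the table held mostly genes that separate the groups, small values were likely for any list. The NF-kB list had such a value with 3 genes higher and 3 lower. The fry values are therefore no evidence that a list moved one way. With an estimated correlation, camera gave the G2/M list an adjusted p of 0.0871. With the GC trend removed, the median shifted by 0.49, 512 genes rose and 506 fell, 191 and 197 of them by at least 2-fold, and 296 of 1600 called genes changed sign, 42 of them as calls. The Hippo list turned to higher (adjusted p = 0.805), PI3K and FOXO reached 0.0385 and G2/M 0.0585. The genes that turned were COL7A1 (-0.59), EPHB2 (-0.0260), GALNT6 (-0.0697), PKP3 (-0.0563), RELB (-0.0143), CXCL8 (0.0419), DCN (0.22), DKK1 (0.11), H3C10 (0.31), IFIT1 (0.10), LUM (0.23), STARD4 (0.0107), STK3 (0.20), USP1 (0.0545) and YAP1 (0.0160). Leaving out each library in turn gave adjusted p of 0.0431 to 0.0595 for the immediate early list, 0.0431 to 0.0595 for CREB and 0.0460 to 0.0852 for PI3K and FOXO. H3C10 ranged from -0.23 to 0.22, and COL7A1 lost its call without shControl library 2 or 3 or shGPER library 1 or 3, as it did with a pseudocount of 0.1. The cause of these moves was not tested. The shared numbers do not pair the libraries: same-numbered deviations correlated at 0.03, -0.09 and 0.01, and not every library correlated best with its own number. With the replicate block 790 genes rose and 832 fell, and 1619 of the 1625 calls held. Rescaling without mitochondrially encoded genes was not run, since the table lists none, and count tests were not run on TPM. Depth is unknown and sets no limit that can be given.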

Other observations

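The tests in this part were chosen after the result was seen, except those of transcript length and of the genes around the zinc finger cluster. Biological process terms in the deposited annotation were compared by the number of called genes that rose and fell, over 131 processes with at least 10 genes. Of these, 9 leaned one way (Fisher's exact test, adjusted p under 0.05). Cell division had 8 genes that rose and 47 that fell (adjusted p = 1.6e-05), and ubiquitin-dependent protein catabolism had 3 and 31 (adjusted p = 5.17e-05). In the latter, the cullin gene CUL3 fell from 49.1 to 11.6 TPM and the ubiquitin ligase subunit SKP1 from 666 to 271 TPM. All 15 genes of the G1/S transition fell (adjusted p = 0.0027), including GMNN, geminin, a brake on replication licensing, from 63.2 to 24.7 TPM, and EZH2, a histone methyltransferase, to 11.1 TPM (log2 fold change -1.05). All 10 genes of anterior/posterior patterning rose (adjusted p = 0.0188), including the retinoic acid receptor RARG, from 5.17 TPM with a log2 fold change of 2.02, and HOXA3, from 20.7 to 48.3 TPM. Within strata of GC content, 0 of the 131 processes passed (adjusted exact p under 0.05), and the smallest unadjusted p was 0.00306.

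Of 21 called genes that the deposited annotation places in the Hippo pathway, 14 rose and 7 fell, where 12.6 would rise from their GC content (exact stratified p = 0.577). TGFB3, a TGF-beta ligand, rose from 3.11 TPM with a log2 fold change of 1.76 and the polarity gene DLG5 from 18.1 to 41.9 TPM, whereas YWHAZ, a 14-3-3 protein, fell from 153 to 39.8 TPM. Among the lists fixed in advance, all 5 PI3K and FOXO genes rose, where GC content gives 1.72. The exact stratified p was 0.00106, or 0.0339 adjusted over 32 lists. One of them, PIK3IP1, at 0.68, 1.22 and 0.93 TPM in shControl, passed the filter only with the help of shGPER. It had little room to be called lower, and the expected number does not allow for this. The adjusted p is therefore not firm. The real split of the libraries gave 1625 genes in limma, and 1 of the 10 splits into 3 and 3 gave as many. The highest of the other splits gave 0 (9 at most at an unadjusted p under 0.05), and 10 splits cannot give a share under 0.05. Because the table held mostly genes that separate these groups, the contrast was largely fixed by that selection and cannot test chance.

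The first pattern is the relation of direction to GC content. Transcript length alone does not account for it, since within each of 5 equal classes of transcript length the rank correlation of GC content with log2 fold change was at least 0.458. A GC-dependent bias of library preparation or sequencing stays open. The slope between 2 libraries of the same group reached 0.12 per 10 points of GC content, against 0.84 between the groups. The rank correlations were closer, at 0.49 between shGPER libraries 1 and 3 and 0.59 between the groups. A bias shared by the libraries of a group and an effect of the knockdown cannot be told apart in this design. An expression change related to base composition, through the hairpin or any other difference between the cells of the groups, may equally underlie it and was not tested.

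The second pattern is a rise of zinc finger genes of chromosome 19. All 19 called genes of this kind rose, including ZNF845, from 1.43 to 4.99 TPM, ZNF317, from 3.26 to 9.52 TPM, and ZNF45, from 5.51 to 12.6 TPM, where 6.81 would rise from their GC content (exact stratified p = 6.54e-12). Of 14 such genes on other chromosomes 7 rose. The exact test treats genes as independent, but 11 of the 19 lie in a cluster, so its p-values are too small if neighbours move together. ZNF836 and ZNF837, at means of 0.74 and 0.727 TPM in shControl, passed the filter only through shGPER and could not be called lower. Reads shared within the group do not explain the rise in full. All 10 members with at most 1.45% of 31-nt words in common with the others, ZNF836 and ZNF837 among them, also rose (4.59 expected, exact stratified p = 8.88e-05). For the other 9 shared reads stay open. Gain of the surrounding segment stays open too: of 32 other called genes within 1 Mb 22 rose, where GC content gives 25.1 (exact stratified p = 0.139), but only 2 of the 32, both higher, lie near the cluster that holds 11 of the 19 genes, and the 10 that fell lie near members outside it. No biological explanation was tested, and the table's selection of genes stays a limit.

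The third pattern is the rise of neuronal and secretory granule genes. The GC trend alone does not account for the rise of SYP, SCG2, SCG3 and CHGB. These stayed higher when the trend was removed, with log2 fold changes of 1.75 to 3.37. For SCG2 and SCG3, which are low in GC content and rose against the trend, the removal could only enlarge the rise. SCG3 and CHGB, at means of 0.14 and 0.233 TPM in shControl, passed the filter only through shGPER and could not be called lower. The number that rose, 4 of 4 with 1.64 expected from GC content, did not pass over the 32 lists (exact stratified p = 0.00502, adjusted 0.0803). A candidate explanation is loss of silencing by REST, the repressor of neuronal genes. Of 21 called genes on a list of REST targets drawn up without sight of their values, 20 rose, including DNER, from 23.4 to 79.4 TPM, against 16.4 expected from GC content (exact stratified p = 0.0331). The expected number does not allow for the filter on low values. Most of the 21 genes, such as CHRNB2 and SCRT1 at means of 0.0833 and 0.03 TPM in shControl, passed it only through shGPER. Such genes could not be called lower. The count was thus largely fixed by the filter, and with its exact p it cannot decide on loss of REST silencing. The rise of the REST targets also cannot be told apart from the GC trend for many of them. Only 11 of the 21 stayed higher once this trend was removed. Their median rise lay at the 97.7th percentile of all GC-matched draws but at the 90.9th percentile of draws from genes that rose.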
